A study of Mus musculus with 18 samples.

How the data were processed

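Gene expression was measured in heart RNA from male mice that carried a Tet-regulated myrAkt1 transgene, an activated form of the kinase Akt1, together with a driver (αMHC-tTA) that is active in heart muscle cells. Whether the atria were part of each sample is not known. The 18 arrays came from 9 samples, each hybridized to chips 430A and 430B of the Affymetrix mouse expression set. The samples fall into 3 groups of 3: hearts taken before AAC, hearts taken 4 weeks later, and hearts taken at 6 weeks with Akt switched on. AAC is the operation used to make the pressure overload named in the design text. Each sample is called a heart; the labels do not say whether RNA was pooled. The labels disagree on 3 points: the titles of the third group give 3 weeks of Akt activation and its descriptions give 2 weeks, its age label of 12 weeks equals that of the 4-week group, and the description of 4-week replicate 3 carries the number 1.

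Per the labels, the authors isolated total RNA with the Ultraspec-II reagent, labelled it with biotin by standard Affymetrix procedures and made the values with MAS5, whose version, chip description file and target are not stated. The deposited unit is intensity, the MAS5 signal of each probe set on a linear scale. The deposited intensities of chip 430A had a trimmed mean (2% off each end) between 500.19 and 500.22 in each of the 9 arrays, so that these arrays had been scaled to 1 common level. Those of chip 430B had a trimmed mean of 122.51 in each array, 4.083 times lower, and were whole multiples of a step of 0.0245, the trace of a further constant factor whose reason is not stated. The pseudocount of 32 therefore weighs on chip 430B as 130.7 would on the scale of chip 430A.

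From these intensities log2(signal + 32) was computed after each array had been brought to the mean trimmed mean of its chip, a step that left the deposited scaling nearly as it was. Of 45265 probe sets, 128 control probe sets were left out of the tests, as were 936 with several gene symbols and 9160 with none, which cannot be assigned to 1 gene. On each chip the 60% of probe sets with the highest mean signal were kept (27083 in all). Where several probe sets remained for a gene, chip 430A was preferred and then the highest mean, which gave 12834 genes, 8265 from chip 430A and 4569 from chip 430B. Symbols came from the deposited platform annotation. The number of arrays, 3 in each group, limits the precision; the median standard error of a log2 difference was 0.185.

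The tests were run in R 4.3.3 with limma 3.58.1. A linear model with the 3 group means was fitted to each chip (lmFit, then eBayes with a trend of the variance on the mean). The 3 contrasts were tested two-sided: 4 weeks after AAC against before AAC, 6 weeks after AAC with Akt on against 4 weeks, and 6 weeks with Akt on against before AAC. Adjusted p-values are by Benjamini-Hochberg over both chips together, and a gene is said to have risen, fallen or changed where its adjusted p is under 0.05. The recovery of known changes was tested on simulated data with the spread of these arrays.

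Gene groups were tested with camera from limma at a preset correlation between genes of 0.01, over 32 lists (19 functional lists and 13 lists of cell type markers) and the 3 comparisons, adjusted over all 96 list tests. The lists were: stress and fetal cardiac genes; adult contraction and calcium handling; cardiac ion channels and gap junctions; fatty acid uptake and oxidation; glycolysis and glucose uptake; the TCA cycle; oxidative phosphorylation; extracellular matrix and fibrosis. Further lists were angiogenic factors and their receptors, FoxO targets with atrophy and autophagy genes, the insulin, IGF and PI3K-Akt-mTOR pathway, ribosome biogenesis and translation factors, and cholesterol and fatty acid synthesis. The others of the functional lists were the integrated stress response and unfolded protein response, heat shock proteins, the cell cycle, immediate early genes, circadian clock genes, and complement and cytokine inflammation. The marker lists covered fibroblasts, endothelium, smooth muscle and pericytes, macrophages, T and B lymphocytes, neutrophils, adipocytes, brown adipocytes, erythroid cells, atrium, skeletal muscle, Schwann cells and neurons, and mesothelium. Several genes stand on more than 1 list, among them Kdr, Flt1, Tek and Tie1 (angiogenic and endothelial) and Col1a1, Col1a2, Col3a1, Dcn and Lum (extracellular matrix and fibroblast). Nppa, Myl4 and Myl7 stand on both the stress and the atrial list. For each list the number of genes past the threshold is given over all genes tested and adjusted over the list alone. Counts cover only the list genes that were tested, such as 13 of 26 for the cell cycle and 15 of 28 for inflammation. Few genes of some marker lists were tested, with 4 of 12 for lymphocytes, 2 of 8 for neutrophils and 3 of 10 for skeletal muscle. Camera with an estimated correlation and fry from limma were run as alternatives.

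The genes named in the text followed a rule: in each comparison the 8 largest rises and the 8 largest falls among changed genes whose 3 hearts of one group all lay above those of the other, leaving out clone, Gm and Rik names; up to 3 members with the smallest p from each list that passed or had a member that passed; and Akt1, Nppa, Nppb, Myh7, Myh6, Acta1, Atp2a2, Vegfa and Angpt2 wherever they could be tested. Angpt2 lay below the filter. All probe sets of Akt1 past the filter are given per heart. Genes named outside the rule are said to have been chosen after their values were seen.

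RNA quality was measured by the ratio of the 3' to the 5' probe set of the β-actin and Gapdh controls, compared by exact two-sided permutation tests, for which the smallest p that 3 hearts against 3 allow is 0.1. The correlation across genes of the first change with the second was set beside 1000 simulated draws of unchanged groups that share the 4-week arrays, and the number of genes changed in opposite directions beside 100 such draws. Genes are called when their replicates lie close, which lowers the slope of the RNA quality test. It was therefore set beside 50 simulated draws in which the ratio caused the whole change, a test added after the result was seen. The form run first added 500 large changes and gave slopes of at least 0.648. The form used for the slope left them out as the stricter one, and they were kept for the class I probe sets. With no female hearts for reference the sex-linked transcripts gave no test of the labels. The 430A and 430B arrays were paired by their replicate numbers. Over 100 shared probe sets, with group means taken out, each 430A array was compared with the 430B arrays of its own group only. In 8 of the 9 hearts it correlated best with its own 430B array, and the r with the own array ran from 0 to 0.5.

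The groups, tests, lists, naming rule and the alternatives for scaling, pseudocount, filter, choice of probe set, variance model, samples in the fit, replicate block, adjustment within each chip, averaging of 4-week replicates 1 and 3, and leaving out each heart were chosen before the data were examined. A further 3 alternatives were chosen after the data had been seen: an atrial marker score as a covariate, leaving out the 4 hearts with the most atrial transcripts, and setting chip 430B to the scale of chip 430A. The same numbers recur across groups without naming the same day or litter in the labels, so the replicate number was used as a block only as an alternative. No count-based model was used, since the values are intensities.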

Results

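The 18 arrays measured transcripts of the heart in male mice with a transgene for activated Akt1 that is driven in heart muscle cells. Each group held 3 hearts: 3 before AAC at the age of 8 weeks, 3 at 4 weeks after AAC, and 3 at 6 weeks after AAC with Akt switched on. The median signal lay between 174.3 and 206.7 on the 430A arrays and between 62.18 and 70.48 on the 430B arrays. The highest 430A signal ran from 39299.5 to 45101 before AAC, from 30634.6 to 31624.6 at 4 weeks and from 30290.9 to 40581.2 with Akt on. On chip 430B it was higher at 4 weeks (23729.5 to 25750.1) than before AAC (19660.7 to 22659.9). List calls at 4 weeks that quantile scaling ended are given below. Replicates correlated with r from 0.963 to 0.979 on chip 430A and from 0.915 to 0.953 on chip 430B. The p-values that follow measure the spread between these samples and no wider population. In simulated data with 200 changed genes, a log2 change of 1 was found in 74.5%, 78.5% and 76.5% of them in the 3 comparisons. A log2 change of 0.5 was found in 1%, 1% and 0% of them. With 2000 changed genes these shares were 92.1%, 92.4% and 91.2% for a change of 1 and 22.3%, 23.5% and 26.2% for a change of 0.5.

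Akt1 itself, the gene of the transgene, was followed through 3 probe sets past the filter. The probe set 1425711_a_at on chip 430A gave log2 signals of 9.53, 8.70 and 9.04 in the hearts before AAC (mean 9.09, SD 0.42, n = 3). It gave 9.24, 9.74 and 9.89 at 4 weeks after AAC (mean 9.62, SD 0.34) and 11.37, 11.89 and 12.68 with Akt on (mean 11.98, SD 0.66). The 3 hearts with Akt on lay above the other 6. The signal was 5.13-fold higher with Akt on than at 4 weeks (log2 2.36, SE 0.30, adjusted p = 0.003 over all probe sets) and 7.41-fold higher than before AAC (adjusted p = 0.00043). The 4-week hearts did not pass against those before AAC (log2 0.53, adjusted p = 0.339). The probe set 1416657_at, which was tested for the gene because of its higher mean, had means of 10.77, 10.36 and 10.37 in the 3 groups. Its log2 changes of −0.41, 0.01 and −0.40 did not pass (adjusted p = 0.185, 0.987 and 0.149). The 430B probe set 1440950_at had means of 7.78, 7.88 and 7.86. The files do not say which of these probe sets lies within the sequence of the transgene.

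**Figure D1:**
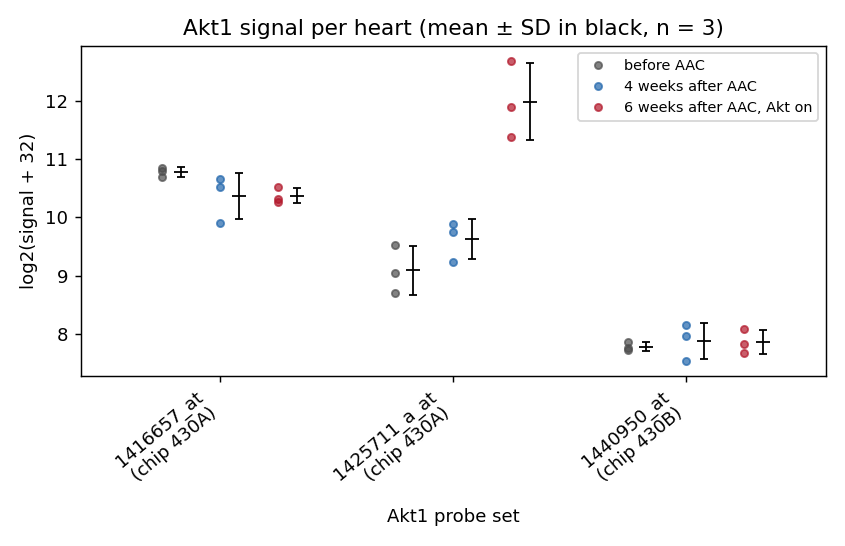
Log2(signal + 32) of the 3 Akt1 probe sets past the filter in each of the 9 hearts, with points for hearts and black bars for the mean and SD of the 3 hearts of a group. The 3 hearts with Akt on lie at 11.37 to 12.68 for 1425711_a_at, above the 6 others at 8.70 to 9.89, while the means of 1416657_at lie at 10.77, 10.36 and 10.37.

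The first comparison, 4 weeks after AAC against before AAC, asks which transcripts changed under pressure overload. Unc119, a trafficking factor for lipid-modified proteins, rose. The class I major histocompatibility gene H2-D1 rose in 4 of its 6 probe sets and fell in 1. Atp5d, a subunit of the mitochondrial ATP synthase, and Rbmxl2, an RNA-binding protein, fell. Acta1, the skeletal α-actin that the stressed heart re-expresses, and Ankrd1, a stress-responsive sarcomere protein, rose as well, while the natriuretic peptides Nppa and Nppb and the myosin genes Myh7 and Myh6 did not pass. The vascular endothelial growth factor receptors Kdr and Flt1 and the co-receptor Nrp2 fell, Flt1 and Nrp2 in 1 of 4 probe sets each. The hearts before AAC were 8 weeks old and no group of the later age went without AAC, so AAC and the passing of time were confounded. A genetic difference of the hearts before AAC, taken up below for the class I probe sets, would be confounded with AAC here and in the third comparison.

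Of 12834 genes, limma called 656 changed at 4 weeks, 342 higher and 314 lower. At an unadjusted p under 0.05 there were 2987, where 642 are expected by chance. The change exceeded 2-fold in 87 genes (55 higher and 32 lower), and the median size of a called change was 0.73 on the log2 scale. The hearts of both groups did not overlap in any of the 656 called genes and in 3962 genes in all, where chance gives 10%. The count of called genes fell when any 1 heart of either group was left out. It was 104, 82 and 37 without before-AAC replicates 1, 2 and 3, and 117, 48 and 503 without 4-week replicates 1, 2 and 3. At an unadjusted p under 0.05 by limma the same fits gave 2452, 2416 and 2395 genes, then 2517, 2346 and 2827. Of the 47 changed genes named in this comparison, 14, 13 and 6 were still called without before-AAC replicates 1, 2 and 3, and 13, 11 and 30 without 4-week replicates 1, 2 and 3. H2-D1, Unc119, Atp5d and Rbmxl2 stayed called without each of the 9 hearts in turn, with adjusted p of at most 2.36e-05, 0.0488, 0.0451 and 0.0461.

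H2-D1 rose 6.55-fold (log2 2.71, SE 0.13, adjusted p = 8.67e-07), from a mean of 9.57 ± 0.12 before AAC to 12.28 ± 0.16 (SD, n = 3), and was higher in 3 of 3 hearts. Of its 6 probe sets, 4 were called in this direction and 1 in the opposite one, with changes from −0.68 to 3.27. Unc119 rose by 1.73 on the log2 scale (SE 0.26, adjusted p = 0.0116). Rbmxl2 fell 3.16-fold (log2 −1.66, SE 0.21, adjusted p = 0.00854). Rbmxl2 at 4 weeks (6.201, 6.02 and 5.915) lay near the floor that the pseudocount sets, as did Unc119 before AAC (6.744, 5.83 and 6.255). The sizes of these changes therefore depend on the pseudocount. The other largest rises were Acad9 (log2 2.20), Myl1 (1.74), Osbpl5 (1.65), Exosc1 (1.52), Klf14 (1.51) and Nmnat1 (1.45). Acad9 was called in 1 of 3 probe sets, with changes from 0.12 to 2.20. The other largest falls were U2af2 (−1.69), Togaram2 (−1.54), Tmem82 (−1.34), Fbp2 (−1.32), Gimap9 (−1.25), Afm (−1.25) and Lgals4 (−1.25). Osbpl5 lost its call without 4-week replicate 2 (adjusted p = 0.0641), Acad9 without before-AAC replicate 1 or 2 or 4-week replicate 1 or 2 (adjusted p up to 0.0698), U2af2 without before-AAC replicate 3 (adjusted p = 0.05), and the others without that heart among others (adjusted p up to 0.149). Without 4-week replicate 1 the change of Fbp2 was −0.81. In this comparison Nmnat1, Aldoa, Dlat, Cox6c, Col5a1, Ccnd1 and Ighm each had a further probe set on the other side of 0 without a call (−0.07 to 0.86).

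Among the 13 stress and fetal cardiac genes 2 rose, 1 fell and 10 did not pass, with the same numbers adjusted over the list alone. The list did not pass (adjusted p = 0.69), with a median of −0.00, a mean of −0.21 and a test that leaned upward. It holds the atrial markers Nppa, Myl4 (log2 −1.38) and Myl7 (−1.90), which were uncalled and differed many-fold between hearts of the same group. Acta1 rose 2.51-fold (log2 1.33, adjusted p = 0.0167), from 12.84 ± 0.56 to 14.17 ± 0.25, and Ankrd1 rose by 0.55 (adjusted p = 0.0335), each higher in 3 of 3 hearts. Nes fell (log2 −0.79, adjusted p = 0.0177). Each of these 3 lost its call without before-AAC replicate 3, 4-week replicate 1 or 4-week replicate 2, Nes and Ankrd1 also without before-AAC replicate 1, and Ankrd1 without before-AAC replicate 2 and 4-week replicate 3 (adjusted p up to 0.105). Nppb (log2 0.29, adjusted p = 0.434), Nppa (−0.71, adjusted p = 0.656), Myh7 (−0.24, adjusted p = 0.74) and Myh6 (−0.16, adjusted p = 0.393) did not pass. Atp2a2, the calcium pump of the sarcoplasmic reticulum, did not pass either (−0.29, adjusted p = 0.138).

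In the list of adult contraction and calcium handling, Tnni3 (log2 −0.49) and Ttn (−0.48) fell and 19 of 21 genes did not pass. Adjusted over the list alone, 1 rose and 9 fell. This list passed with a median of −0.27 (adjusted p = 0.00158; adjusted p = 0.645 with an estimated correlation), but its direction flipped under quantile scaling (median 0.01, adjusted p = 0.555), and its call ended when all probe sets of a gene were averaged (adjusted p = 0.0832). Tnni3 and Ttn were uncalled without any 1 of before-AAC replicates 1, 2 and 3 and 4-week replicates 1 and 2, and Ttn also without Akt-on replicate 3 (adjusted p up to 0.163).

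Oxidative phosphorylation genes, which supply most of the energy of the beating heart, fell as a list, with a median of −0.29 (adjusted p = 6.63e-10; adjusted p = 0.624 with an estimated correlation), a call that quantile scaling ended (median −0.04, adjusted p = 0.385). Of the 46 genes, 11 fell and 35 did not pass, and 21 fell adjusted over the list alone. Atp5d fell 1.75-fold (log2 −0.81, SE 0.11, adjusted p = 0.00978), while its other probe set gave −0.21 without a call. Cox6c (−0.67) and Atp5g3 (−0.51) fell too, both uncalled without any 1 of before-AAC replicates 1, 2 and 3 and 4-week replicates 1 and 2 (adjusted p up to 0.0709); the mean of all Cox6c probe sets gave 0.10 instead (adjusted p = 0.77; 0.00597 to 0.77 over its alternatives).

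Fatty acid uptake and oxidation had a median of −0.17 (adjusted p = 0.00441; adjusted p = 0.712 with an estimated correlation), a call that ended under quantile scaling (−0.09, adjusted p = 0.394) and without 4-week replicate 1 (−0.06, adjusted p = 0.279). Of its 28 genes 5 fell and 23 did not pass, also adjusted over the list alone. Etfb fell by 0.70 (log2 −0.70, adjusted p = 0.0112, and 0.0544 without before-AAC replicate 3), and Hadh (−0.59) and Ucp3 (−0.85) fell. In the TCA cycle Dld (0.89) and Dlat (0.78) were among 3 genes that rose, Sdhb (−0.60) was among 3 that fell, and 13 of 19 did not pass. Adjusted over the list alone, 5 rose and 4 fell. The list did not pass (adjusted p = 0.913), with a median of −0.05, a mean of 0.05 and a test that leaned upward. Of 17 genes of glycolysis and glucose uptake, Aldoa (−0.38, reversed under quantile scaling) and Ldhb (−0.55) fell and 15 did not pass (3 fell adjusted over the list alone; list adjusted p = 0.272). Hadh, Ucp3, Dld, Dlat, Sdhb, Aldoa and Ldhb were each uncalled without before-AAC replicate 2 or 3, among other hearts (adjusted p up to 0.157).

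Angiogenic factors and their receptors had a median of −0.33 (adjusted p = 0.000248; adjusted p = 0.128 with an estimated correlation). Of 19 genes 4 fell and 15 did not pass, and 7 fell adjusted over the list alone. Kdr fell 1.92-fold (log2 −0.94, SE 0.16, adjusted p = 0.0153), from 11.98 ± 0.10 to 11.04 ± 0.33, and was lower in 3 of 3 hearts. Its adjusted p was 0.0633 without before-AAC replicate 3. Flt1 (−0.65, adjusted p = 0.0229) and Nrp2 (−0.71, adjusted p = 0.0236) fell too, and each lost its call without any 1 of before-AAC replicates 1, 2 and 3 and 4-week replicates 1 and 2 (adjusted p up to 0.0862). Each had 4 probe sets with 1 called, and their changes ran from −0.65 to −0.04 in Flt1 and from −0.71 to −0.07 in Nrp2. Vegfa did not pass (log2 −0.09, adjusted p = 0.774), and Angpt2 lay below the filter. The endothelial markers, which share Kdr and Flt1 with that list, had a median of −0.34 (adjusted p = 0.000649; adjusted p = 0.2 with an estimated correlation). Of these 12 genes 2 fell and 10 did not pass, also adjusted over the list alone.

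Cell cycle genes had a median of −0.49 (adjusted p = 0.00279; adjusted p = 0.624 with an estimated correlation), a call that ended without a filter (0.187) and among the 40% of probe sets with the highest signal (0.132). Cdk1 (log2 −1.14) and Ccnd1 (from 11.38 to 10.37) fell and 11 of 13 did not pass, also adjusted over the list alone. The integrated stress response and unfolded protein response had a median of −0.28 (adjusted p = 0.0169; adjusted p = 0.624 with an estimated correlation), a call that ended among the 40% of probe sets with the highest signal (−0.12, adjusted p = 0.106) and without 4-week replicate 2 (0.0608). Phgdh (−0.66), Sdf2l1 (−0.76) and Hsp90b1 (−0.63) fell and 16 of 19 did not pass (5 fell adjusted over the list alone). Complement and cytokine inflammation had a median of −0.33 (adjusted p = 0.045; adjusted p = 0.624 with an estimated correlation), a call that quantile scaling ended (−0.27, adjusted p = 0.0625). It also ended without before-AAC replicate 1 (0.0533) or 2 (0.0523) and without 4-week replicate 1 (0.0562) or 2 (0.0931) and with chip 430B on the scale of chip 430A (0.0657). Cxcl16 (−0.95) was the 1 of 15 that fell; 1 rose and 3 fell adjusted over the list alone.

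In the extracellular matrix list Tgfb1 (−0.75) and Col5a1 (−0.59) fell and 36 of 38 did not pass, also adjusted over the list alone; the list did not pass (median −0.18, adjusted p = 0.121). Cat (0.82) was the 1 of 24 FoxO, atrophy and autophagy genes that rose, also adjusted over the list alone. That list did not pass (adjusted p = 0.421), with a median of −0.01, a mean of 0.06 and a test that leaned upward. The insulin, IGF and PI3K-Akt-mTOR list did not pass (adjusted p = 0.749), with a median of −0.03, a mean of 0.02 and a test that leaned upward. Of 21 ribosome biogenesis and translation factors Eif4e (0.53) rose and Eef2 (−0.39) fell (4 and 2 adjusted over the list alone; median 0.09, adjusted p = 0.288). Of 4 lymphocyte markers Ighm (−0.67) fell (2 adjusted over the list alone; median −0.35, adjusted p = 0.363). Tgfb1, Col5a1, Cat, Eif4e, Eef2, Ighm, Cdk1, Ccnd1, Phgdh, Sdf2l1, Hsp90b1 and Cxcl16 were each uncalled without before-AAC replicate 3, and all but Cdk1 and Tgfb1 without 4-week replicate 2 (adjusted p up to 0.129 without any 1 heart).

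The other lists did not pass at 4 weeks. Among them were ion channels (median −0.11, adjusted p = 0.749), cholesterol and fatty acid synthesis (−0.00, adjusted p = 0.749), heat shock proteins (0.13, adjusted p = 0.282), immediate early genes (−0.02, adjusted p = 0.823) and circadian clock genes (−0.18, adjusted p = 0.775). The markers of fibroblasts (−0.22, adjusted p = 0.349), smooth muscle and pericytes (−0.42, adjusted p = 0.0794), macrophages (−0.17, adjusted p = 0.124) and neutrophils (0.37, adjusted p = 0.775) did not pass. Adipocyte (−0.15, adjusted p = 0.857), brown adipocyte (−0.24, adjusted p = 0.395) and erythroid markers (−0.21, adjusted p = 0.616) had 2 genes measured each. Skeletal muscle (−0.27, adjusted p = 0.559) and mesothelial markers (0.01, adjusted p = 0.749) had 3 each, and those of Schwann cells and neurons 5 (−0.33, adjusted p = 0.363).

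RNA quality differed along with the groups. The 3'/5' ratio of β-actin on chip 430A was 1.82 ± 0.296 before AAC and 1.19 ± 0.042 at 4 weeks (SD, n = 3; exact two-sided permutation p = 0.1, the smallest these group sizes allow). That of Gapdh was 1.19 ± 0.122 and 0.862 ± 0.031 (exact two-sided permutation p = 0.1).

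The amount of atrial transcripts differed between hearts of the same group. Of the atrial markers Sln, Myl4 and Myl7 were named after their values were seen. Sln, the sarcolipin of atrial muscle, had log2 signals of 5.84, 14.21 and 12.91 before AAC, 13.49, 8.56 and 5.18 at 4 weeks and 13.50, 5.49 and 9.30 with Akt on. The atrial myosin light chain Myl4 gave 8.84, 14.37 and 13.38, then 14.07, 10.30 and 8.07, then 14.22, 9.61 and 11.90 in the same hearts. Myl7 ranged from 8.33 to 13.99 before AAC and from 6.05 to 13.85 at 4 weeks. The 9 atrial markers, Nppa among them, had medians of −0.71, 0.49 and −0.50 in the 3 comparisons and did not pass as a list (adjusted p = 0.262, 0.599 and 0.627). By limma 0 of the 9 were called in each comparison, and 0 of the 9 had an unadjusted p under 0.05. Nppa, Myl4 and Myl7 are also on the stress list. The SD of Nppa was 1.73 before AAC and 1.51 at 4 weeks.

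**Figure D2:**
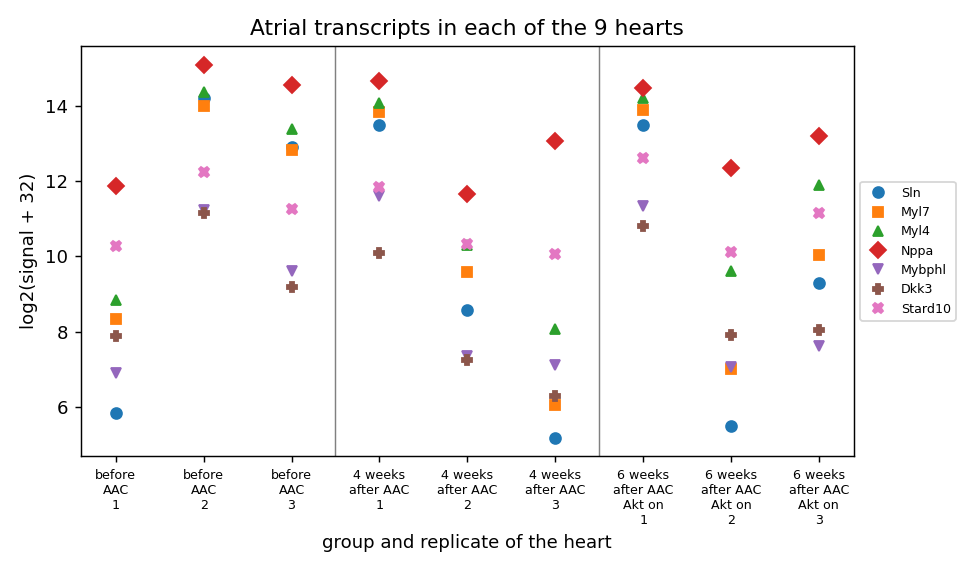
Log2(signal + 32) of 7 atrial marker genes in each of the 9 hearts, with a marker and colour for each gene and grey lines between the groups. Sln ranges from 5.84 to 14.21 within the hearts before AAC, from 5.18 to 13.49 at 4 weeks and from 5.49 to 13.50 with Akt on.

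The second comparison, 6 weeks after AAC with Akt on against 4 weeks, asks which transcripts changed once Akt had been activated after AAC. Cilp, Postn, Mmp14 and the collagen genes Col1a1, Col1a2 and Col3a1, products mainly of cardiac fibroblasts, rose, while the transgene is driven in heart muscle cells. These collagen genes did not stay called without each heart in turn. Mylk4 and Myom2, a kinase and an M-band protein of the sarcomere, and the potassium channel genes Kcnip2 and Abcc9 fell. Slc2a4, the insulin-responsive glucose transporter, the insulin receptor substrate Irs1, the isoform Akt2 and the FoxO family member Foxo4 fell, while Igfbp5 rose and the insulin, IGF and PI3K-Akt-mTOR list as a whole did not pass. Cdk1, a kinase that drives mitosis, rose, and Dbp and Nr1d2, output genes of the circadian clock, fell. No group was sampled at 6 weeks without Akt, and all mice carried the transgene and its driver. The activation of Akt, the step that switched the Tet-regulated transgene on and the passing of time were therefore confounded.

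Of 12834 genes, limma called 553 changed, 228 higher and 325 lower, and 2609 had an unadjusted p under 0.05. The change exceeded 2-fold in 158 genes (80 higher and 78 lower), with a median size of 0.81. The hearts of both groups did not overlap in any of the 553 called genes and in 2978 genes in all, where chance gives 10%. The count was 303 and 201 without 4-week replicates 2 and 3 and 278 without Akt-on replicate 2. Of the 56 changed genes named in this comparison, 47, 35 and 26 were still called without 4-week replicates 1, 2 and 3, and 42, 33 and 41 without Akt-on replicates 1, 2 and 3. Without before-AAC replicates 1, 2 and 3, which enter through the shared spread, 48, 50 and 46 were. The 22 that stayed called without each of the 9 hearts were Abcc9, Akt2, Bex1, Casq1, Cdk1, Cilp, Dbp, Doc2g, Foxo4, Irs1, Klf15, Mmp14, Mylk4, Myom2, Nr1d2, Opn3, Postn, Ryr1, Scd2, Sesn3, Slc2a4 and Smim27.

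Extracellular matrix and fibrosis genes rose as a list, with a median of 0.92 (adjusted p = 9.23e-20; adjusted p = 0.582 with an estimated correlation). Of 38 genes, 19 rose and 19 did not pass, 29 rose adjusted over the list alone, and 36 had a change above 0. Postn, a matricellular protein of activated fibroblasts, rose 5.03-fold (log2 2.33, SE 0.34, adjusted p = 0.00349), from 10.32 ± 0.79 to 12.65 ± 0.47 (SD, n = 3). Cilp rose 6.77-fold (log2 2.76, SE 0.41, adjusted p = 0.00349). Both were higher in 3 of 3 hearts. Mmp14, a membrane-bound matrix metalloproteinase, rose by 1.11 (adjusted p = 0.00313), called in 1 of 3 probe sets with changes from 0.25 to 1.11. Col1a1 (1.26), Col1a2 (1.21) and Col3a1 (1.14) rose but lost their calls without 4-week replicate 3 (adjusted p = 0.0581 in Col3a1), and Col1a1 and Col1a2 also without 4-week replicate 2 or Akt-on replicate 2 (adjusted p up to 0.125). Further risers, named after their values were seen, were Col8a1 (1.94), Ltbp2 (1.56), Col5a2 (1.49), Eln (1.42), Timp1 (1.41), Mfap5 (1.33), Thbs1 (1.24), Fn1 (1.21) and Lox (1.12). Col1a1, Col1a2 and Col3a1 were also the 3 of 12 fibroblast markers that rose, also adjusted over the list alone. That list did not pass (median 0.13, adjusted p = 0.272).

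Mylk4 fell by 3.32 on the log2 scale (SE 0.26, adjusted p = 8.21e-05), from 10.99 ± 0.49 to 7.67 ± 0.47 (SD, n = 3), and was lower in 3 of 3 hearts. Myom2 fell 8.46-fold (log2 −3.08, SE 0.48, adjusted p = 0.00493), and 3 of its 3 probe sets fell. Smim27 (−2.14, adjusted p = 0.000176), Doc2g (−2.12) and Bex1 (−2.12, adjusted p = 0.000969) fell too. So did Gnb3 (−2.48; adjusted p = 0.0562 without Akt-on replicate 2) and Gbp6 (−2.05; adjusted p = 0.0652 without 4-week replicate 3). Opn3, an opsin, rose 5.19-fold (log2 2.38, adjusted p = 0.000858). Ryr1, the calcium release channel of skeletal muscle, rose by 2.20 (adjusted p = 0.00398), along with Casq1, its calsequestrin partner (1.30, adjusted p = 0.00389). Stbd1 (2.71), Sh3gl3 (2.63) and Cnn1 (2.04) rose but were uncalled without Akt-on replicate 2, and Angptl4 (2.27) without Akt-on replicate 1 or 4-week replicate 3 (adjusted p up to 0.122).

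Nppb fell 1.99-fold (log2 −0.99, adjusted p = 0.022; up to 0.0877 without 4-week replicate 2 or 3). It was the 1 of 13 stress and fetal genes that changed, also adjusted over the list alone. The list did not pass (adjusted p = 0.749), with a median of 0.18, a mean of 0.05 and a test that leaned downward. Nppa (0.21, adjusted p = 0.921), Myh7 (−0.74, adjusted p = 0.273), Myh6 (−0.22, adjusted p = 0.254), Acta1 (0.37, adjusted p = 0.421), Atp2a2 (0.03, adjusted p = 0.917) and Vegfa (−0.40, adjusted p = 0.177) did not pass. Casq2 (0.50) was the 1 of 21 contraction genes that rose, also adjusted over the list alone (median 0.05, adjusted p = 0.395), and was uncalled without 8 of the 9 hearts (adjusted p up to 0.102).

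Ion channel and gap junction genes had a median of −0.52 (adjusted p = 0.00441; adjusted p = 0.624 with an estimated correlation; −0.32 and 0.08 without Akt-on replicate 2). Of 18 genes 5 fell and 13 did not pass, and 1 rose and 8 fell adjusted over the list alone. Abcc9, a subunit of the ATP-sensitive potassium channel, fell 3.23-fold (log2 −1.69, adjusted p = 0.00721). Kcnip2, a subunit of the channel of the transient outward potassium current (−2.46), Kcnj8 (−0.82) and Kcnv2 (−0.72) fell but were uncalled without Akt-on replicate 2, among other hearts (adjusted p up to 0.103). Without 4-week replicate 3 the change of Kcnip2 was −1.52 and still called, and its other probe set gave −4.94.

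In the insulin, IGF and PI3K-Akt-mTOR pathway Irs1 fell 2.29-fold (log2 −1.20, SE 0.15, adjusted p = 0.00184), from 10.51 ± 0.08 to 9.31 ± 0.17. Akt2 fell (−0.76, adjusted p = 0.00752), and Igfbp5 rose (1.27; adjusted p up to 0.0665 without 4-week replicate 2 or 3). Of the 26 genes 2 rose and 2 fell, also adjusted over the list alone, and the list did not pass (median −0.12, adjusted p = 0.421). FoxO targets, atrophy and autophagy genes had a median of −0.24 (adjusted p = 0.000549; adjusted p = 0.582 with an estimated correlation). Of 24 genes 5 fell, 1 rose and 18 did not pass; 8 fell and 1 rose adjusted over the list alone. Klf15 (log2 −1.37, adjusted p = 0.0101) and Foxo4 (−0.78, adjusted p = 0.00608) fell, and Sesn3 rose (1.10, adjusted p = 0.00682).

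Slc2a4 fell 2.10-fold (log2 −1.07, SE 0.12, adjusted p = 0.000969) and was lower in 3 of 3 hearts. Pkm, a pyruvate kinase, rose (0.63; adjusted p up to 0.0652 without 4-week replicate 3 or Akt-on replicate 2). The other 15 of 17 glycolysis genes did not pass (3 rose and 2 fell adjusted over the list alone). The list did not pass (adjusted p = 0.823), with a median of 0.00, a mean of −0.01 and a test that leaned downward. Of 28 genes of fatty acid oxidation 3 rose and 2 fell (6 and 2 adjusted over the list alone; median 0.09, adjusted p = 0.395). Slc25a20 (0.79) and Cpt2 (0.48) rose and Lpl (−0.44) fell, each uncalled without 4-week replicate 2 or Akt-on replicate 3, among other hearts (adjusted p up to 0.109).

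Oxidative phosphorylation stood at the edge of the threshold, with a median of −0.06 (adjusted p = 0.0497; adjusted p = 0.828 with an estimated correlation), a call that ended under quantile scaling (0.0591) and under scaling to the 75th percentile (0.0687). It also ended without before-AAC replicates 1, 2 and 3 (0.0533, 0.0625 and 0.0544), without 4-week replicates 2 and 3 (0.0888 and 0.663, the latter with a median of −0.00) and without Akt-on replicates 1 and 3 (medians −0.01 and −0.03, adjusted p = 0.594 and 0.12). Without Akt-on replicate 2 the median was −0.13 (adjusted p = 0.000239). In all it ended under 20 of 28 alternatives. Ndufs1 (−0.53) was the 1 of 46 that fell and was uncalled without 7 of the 9 hearts (adjusted p up to 0.126). By limma 0 fell adjusted over the list alone and 8 at an unadjusted p under 0.05.

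Cell cycle genes rose as a list (median 0.67, adjusted p = 9.15e-06; adjusted p = 0.582 with an estimated correlation), a call that ended among the 40% of probe sets with the highest signal (0.106). Of the 13 genes tested out of 26 on the list, 3 rose and 10 did not pass, 7 rose adjusted over the list alone, and 13 changes lay above 0. Mki67, Ccnb1 and Aurkb were among those not tested. Cdk1 rose 3.27-fold (log2 1.71, SE 0.25, adjusted p = 0.00349). Ccna2 rose by 1.05 (adjusted p up to 0.0567 without 4-week replicate 3 or Akt-on replicate 2) and Aurka by 0.73 (uncalled without each of the 9 hearts, adjusted p up to 0.106).

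Circadian clock genes had a median of −0.54 (adjusted p = 0.0018; adjusted p = 0.582 with an estimated correlation). Of 13 genes 3 fell and 10 did not pass, and 1 rose and 6 fell adjusted over the list alone. Dbp fell 2.87-fold (log2 −1.52, SE 0.21, adjusted p = 0.00333) and Nr1d2 by 0.86 (log2 −0.86, adjusted p = 0.00562). Of 2 Nr1d2 probe sets 1 was called, and the other gave −0.26. Per3 fell too (−0.94, adjusted p = 0.0486) but was uncalled without 7 of the 9 hearts (adjusted p up to 0.168), and its probe set of highest signal over both chips gave 0.06.

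Heat shock proteins had a median of −0.21 (adjusted p = 0.00612; adjusted p = 0.582 with an estimated correlation), a call that ended without Akt-on replicate 1 (−0.12, adjusted p = 0.0851), among the 40% of probe sets with the highest signal (0.0576) and without the 4 hearts with the most atrial transcripts (0.164). Dnajb1 (−0.89) and Hspe1 (−0.72) fell and 14 of 16 did not pass (1 rose and 2 fell adjusted over the list alone). Immediate early genes had a median of −0.39 (adjusted p = 0.0338; adjusted p = 0.712 with an estimated correlation), a call that ended under 10 of 28 alternatives. Among these were quantile scaling (0.05), no filter (median −0.07, 0.116), the 40% of probe sets with the highest signal (0.0583), 4-week replicates 1 and 3 averaged (0.101), and the 4 hearts with the most atrial transcripts left out (0.123). It also ended without 4-week replicates 1 and 3 (medians −0.24 and −0.23, adjusted p = 0.102 and 0.151) or Akt-on replicate 1 (0.09). Dusp1 (−1.02) was the 1 of 12 that fell (2 adjusted over the list alone). Scd2, a fatty acid desaturase, rose 2.82-fold (log2 1.49, adjusted p = 0.00817). Fdps (0.71) rose and Fdft1 (−0.75) fell, and 13 of 16 cholesterol and fatty acid synthesis genes did not pass (4 rose and 1 fell adjusted over the list alone; median 0.17, adjusted p = 0.208). Of 19 stress response genes Mthfd2 rose (0.79) and Herpud1 fell (−0.98; 3 and 2 adjusted over the list alone; median 0.11, adjusted p = 0.367). Of 15 inflammation genes Ccl8 rose (0.82) and Cxcl12 fell (−1.03; 2 and 1 adjusted over the list alone; median 0.17, adjusted p = 0.459). Vegfd (0.87) and Angptl4 were the 2 of 19 angiogenic genes that rose (2 rose and 2 fell adjusted over the list alone). That list did not pass (adjusted p = 0.279), with a median of −0.16, a mean of 0.02 and a test that leaned downward. Dnajb1, Hspe1, Dusp1, Fdps, Fdft1, Mthfd2, Herpud1, Ccl8, Cxcl12, Vegfd and Angptl4 were each uncalled without 4-week replicate 3 (adjusted p up to 0.136 without any 1 heart).

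The other lists did not pass in the second comparison. Among them were the TCA cycle (median −0.15, adjusted p = 0.0835), ribosome biogenesis and translation factors (−0.05, adjusted p = 0.616), endothelial markers (−0.23, adjusted p = 0.0673) and macrophage markers (0.26, adjusted p = 0.0673). Smooth muscle and pericyte markers, of which Cnn1 rose, had a median of −0.15, a mean of 0.11 and a test that leaned downward (adjusted p = 0.749). Lymphocyte (0.29, adjusted p = 0.346), neutrophil (0.66, adjusted p = 0.357), adipocyte (−0.25, adjusted p = 0.775) and erythroid markers (−0.23, adjusted p = 0.823) did not pass. Of 2 brown adipocyte markers Cidea rose (0.63; uncalled without 4-week replicate 3, among other hearts, adjusted p up to 0.107; list median 0.08, adjusted p = 0.823), and of 3 skeletal muscle markers Casq1 rose (median 0.27, adjusted p = 0.121). Schwann and neuron (0.34, adjusted p = 0.559) and mesothelial markers (−0.30, adjusted p = 0.476) did not pass. The 3'/5' ratio of β-actin on chip 430A was 1.19 ± 0.042 at 4 weeks and 1.12 ± 0.093 with Akt on (SD, n = 3; exact two-sided permutation p = 0.4).

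**Figure D3:**
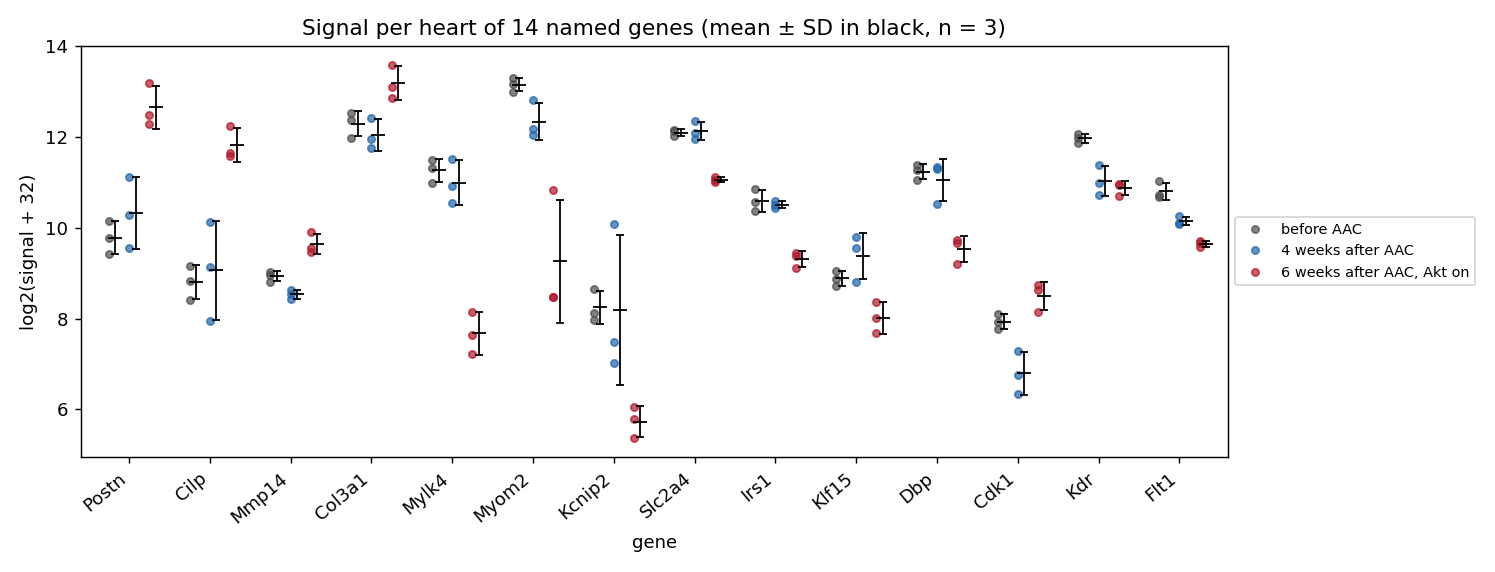
Log2(signal + 32) of 14 named genes in each of the 9 hearts, with points for hearts and black bars for the mean and SD of the 3 hearts of a group. Postn has means of 9.78, 10.32 and 12.65 before AAC, at 4 weeks and with Akt on, Mylk4 of 11.27, 10.99 and 7.67, and Kdr of 11.98, 11.04 and 10.87.

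The third comparison, 6 weeks after AAC with Akt on against before AAC, asks how far the hearts with Akt on lay from the state before the operation. Myom2, Mylk4 and the carboxylesterase Ces1d fell, and Postn, Cilp and Mfap4, a protein of elastic fibres, rose. Flt1, Kdr and Nrp1, receptors of vascular endothelial growth factor, Gja1, the main gap junction protein of the ventricle, and Slc2a4 and Irs1 fell. Subunits of the respiratory chain such as Ndufv1, Ndufa1 and Cox8b fell. Acta1 was higher and Nppb lower than before AAC. The comparison spans AAC, 6 weeks of time, the step that switched the Tet-regulated transgene on and the activation of Akt together.

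Of 12834 genes, limma called 1930 changed, 930 higher and 1000 lower, and 3757 had an unadjusted p under 0.05. The change exceeded 2-fold in 393 genes (216 higher and 177 lower), with a median size of 0.71. The hearts of both groups did not overlap in 1911 of the called genes and in 4288 genes in all, where chance gives 10%. The count was 1228, 1175 and 973 without before-AAC replicates 1, 2 and 3, and 1264 and 1162 without Akt-on replicates 2 and 3. Of the 82 changed genes named in this comparison, 59 stayed called without each of the 9 hearts in turn. Without before-AAC replicates 1, 2 and 3 there were 66, 70 and 66 of the 82, and without Akt-on replicates 1, 2 and 3 there were 74, 72 and 64. Of 476 genes with several called probe sets, 39 had probe sets called in opposite directions, among them Dlat, Stat3 and Myh6; in the first comparison there were 10 such genes of 108. Gja1, Akt2, Ddit3, Hspa8, Ccnd1, Nr1d2, Rgs5 and Ckm each had a further probe set above 0 without a call (0.01 to 0.61).

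Myom2 fell 14.9-fold (log2 −3.90, SE 0.48, adjusted p = 0.000758), from 13.16 ± 0.15 to 9.26 ± 1.36 (SD, n = 3), and Mylk4 fell 12.1-fold (log2 −3.60, SE 0.26, adjusted p = 1.69e-05). Both were lower in 3 of 3 hearts. Ces1d (−3.70), Doc2g (−2.76), the long noncoding RNA Neat1 (−2.43; 0.17 in its other probe set), Smim27 (−2.35) and Lrrc4b (−2.29) fell as well. Mfap4 rose 12.3-fold (log2 3.63, adjusted p = 0.0101), Slc17a7 by 3.56, Stbd1 by 2.90, Myl1 by 2.81, Fam122b by 2.59 and Unc119 by 2.44. Before AAC Mfap4 (5.53, 6.54 and 5.68) lay near the floor that the pseudocount sets, so its fold depends on the pseudocount. Acta1 rose 3.25-fold (log2 1.70, SE 0.24, adjusted p = 0.00124), from 12.84 ± 0.56 to 14.54 ± 0.27. Nes (−0.50) and Nppb (−0.70, adjusted p = 0.0387) fell, both uncalled without before-AAC replicate 1 or 3, 4-week replicate 2 or Akt-on replicate 3 (adjusted p up to 0.135; Nppb −0.45 without the last). These were the 3 of 13 stress and fetal genes that changed (2 rose and 4 fell adjusted over the list alone; median −0.29, adjusted p = 0.913). Myh7 (−0.98, adjusted p = 0.0873), Nppa (−0.50, adjusted p = 0.74), Atp2a2 (−0.26, adjusted p = 0.134) and Vegfa (−0.49, adjusted p = 0.0553) did not pass. Myh6 fell (−0.38, adjusted p = 0.0298), but another of its probe sets rose by 0.91, and the call ended without before-AAC replicate 2 or 3 or Akt-on replicate 1 or 3 (adjusted p up to 0.119). With Tnni3 (−0.48), Ttn (−0.56) and another gene it was among 4 fallen of 21 contraction genes, of which 2 rose (9 and 3 adjusted over the list alone; median −0.29, adjusted p = 0.0794).

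Extracellular matrix genes rose as a list (median 0.71, adjusted p = 1.24e-09; adjusted p = 0.624 with an estimated correlation). Of 38 genes 16 rose, 1 fell and 21 did not pass; 20 rose and 2 fell adjusted over the list alone. Postn rose 7.34-fold (log2 2.88, SE 0.34, adjusted p = 0.000616), Cilp 8.12-fold (log2 3.02, adjusted p = 0.00102) and Thbs1 by 1.30 (adjusted p = 0.00137). Among 12 fibroblast markers Col3a1 (0.89) and Col1a2 (1.02) rose, both uncalled without before-AAC replicate 1 or Akt-on replicate 2 (adjusted p up to 0.0644). Gsn fell (−0.87; 0.0537 without Akt-on replicate 3), and the list did not pass (2 rose and 2 fell adjusted over the list alone; median 0.13, adjusted p = 0.749).

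The angiogenic list had a median of −0.50 (adjusted p = 0.000248; adjusted p = 0.128 with an estimated correlation). Of its 19 genes 10 fell, 1 rose and 8 did not pass; 12 fell and 1 rose adjusted over the list alone. The endothelial markers had a median of −0.55 (adjusted p = 4.87e-05; adjusted p = 0.128 with an estimated correlation). Of these 12 genes 6 fell and 6 did not pass, and 9 fell adjusted over the list alone. Flt1 fell 2.22-fold (log2 −1.15, SE 0.13, adjusted p = 0.000523), from 10.80 ± 0.19 to 9.65 ± 0.07, and Kdr fell 2.15-fold (log2 −1.11, SE 0.16, adjusted p = 0.0015). Of 4 Flt1 probe sets 2 were called, with changes from −1.15 to −0.28. Nrp1 (−0.76, adjusted p = 0.00306) and Egfl7 (−0.67, adjusted p = 0.0061) fell as well, and these 4 genes were each lower in 3 of 3 hearts.

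Oxidative phosphorylation genes fell as a list, with a median of −0.38 (adjusted p = 3.1e-12; adjusted p = 0.624 with an estimated correlation), or −0.14 under quantile scaling (adjusted p = 0.0167). Of 46 genes 22 fell and 24 did not pass, and 29 fell adjusted over the list alone. Among them were Ndufv1 (−0.66, adjusted p = 0.00154), Ndufa1 (−0.65, adjusted p = 0.00162) and Cox8b (−0.72, adjusted p = 0.00176). Of 19 TCA cycle genes 6 fell, among them Sdhb (−0.70) and Idh3g (−0.49), and 2 rose, among them Dlat (0.95; 7 and 2 adjusted over the list alone; median −0.23, adjusted p = 0.301). Slc2a4 fell 2.05-fold (log2 −1.04, SE 0.12, adjusted p = 0.000529). With Ldhb (−0.73) it was among 5 fallen of 17 glycolysis genes, of which 3 rose, Pgam1 (0.76) among them (7 and 4 adjusted over the list alone; median −0.10, adjusted p = 0.282). Of 28 fatty acid genes 4 fell, among them Lpl (−0.73, adjusted p = 0.00113) and Etfb (−0.56), and 2 rose (5 and 2 adjusted over the list alone; median −0.14, adjusted p = 0.143). Slc25a20, which rose by 0.63, was uncalled without before-AAC replicate 1 or 2 or Akt-on replicate 1 or 3 (adjusted p up to 0.0861).

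Irs1 (−1.29, adjusted p = 0.000523), Akt2 (−0.79, adjusted p = 0.00252), Foxo4 (−0.76), Pink1 (from 12.20 to 11.20) and Sesn1 (−0.72) fell. Sesn1 was called in 1 of 4 probe sets, with changes from −0.72 to −0.01. Ddit4, an inhibitor of mTOR signalling, rose 3.01-fold (log2 1.59, adjusted p = 0.00179). Of the 26 genes of the insulin, IGF and PI3K-Akt-mTOR list 4 rose and 2 fell, also adjusted over the list alone (median −0.15, adjusted p = 0.749). Of the 24 FoxO, atrophy and autophagy genes 2 rose and 7 fell (2 and 9 adjusted over the list alone; median −0.15, adjusted p = 0.0923). Ion channel and gap junction genes had a median of −0.35 (adjusted p = 0.0152; adjusted p = 0.712 with an estimated correlation; −0.14 and 0.122 without Akt-on replicate 2). Of 18 genes 7 fell, 1 rose and 10 did not pass; 8 fell and 1 rose adjusted over the list alone. Gja1 fell 2.27-fold (log2 −1.18, adjusted p = 0.00193), and Kcnj8 (−1.17), Kcnv2 (−1.02) and Kcnip2 (−2.52; 0.0551 without before-AAC replicate 1) fell. Circadian clock genes had a median of −0.40 (adjusted p = 0.0145; adjusted p = 0.624 with an estimated correlation). Dbp (−1.70), Per3 (−1.51) and Nr1d2 (−0.88) were among 5 fallen, and 8 of 13 did not pass (1 rose and 6 fell adjusted over the list alone). Immediate early genes had a median of −0.47 (adjusted p = 0.0451; adjusted p = 0.712 with an estimated correlation), a call that ended without a filter (−0.18, adjusted p = 0.147), among the 40% of probe sets with the highest signal (0.0888), with eBayes without trend (0.0562), with the atrial score as a covariate (0.0505) and with chip 430B on the scale of chip 430A (0.0596). It also ended without before-AAC replicate 2 (−0.27, adjusted p = 0.278) or Akt-on replicate 1 (adjusted p = 0.143). Dusp1 (−0.89) was the 1 of 12 that fell, also adjusted over the list alone, and was uncalled without before-AAC replicate 2 or Akt-on replicate 3 (adjusted p up to 0.0606).

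Other lists with changed members did not pass in the third comparison. Of 16 cholesterol and fatty acid genes Fdps (1.05), Scd2 (1.51) and Fasn (1.46) rose and 1 fell (3 and 2 adjusted over the list alone; median 0.05, adjusted p = 0.616). Of 13 cell cycle genes Ccna2 (0.72) rose and Ccnd1 (−0.80) fell, also adjusted over the list alone (median 0.31, adjusted p = 0.279). Of 21 translation genes Wdr12 (0.79) and Eif4e (0.47) rose and Eef2 (−0.48) fell, also adjusted over the list alone (median 0.06, adjusted p = 0.659). Of 19 stress response genes 2 rose, among them Mthfd2 (0.72), and 3 fell, among them Herpud1 (−0.98) and Ddit3 (−0.72), also adjusted over the list alone (median −0.23, adjusted p = 0.248). Of 16 heat shock proteins Hspb6 (0.88) rose and 3 fell, among them Hspe1 (−0.69) and Hspa8 (−0.52), also adjusted over the list alone (median −0.27, adjusted p = 0.341). Of 15 inflammation genes 2 rose, among them Stat3 (0.79), and Cxcl12 (−1.70) and Nfkbia (−0.78) fell, also adjusted over the list alone (median −0.22, adjusted p = 0.346). Fasn, Ccna2, Wdr12, Eif4e, Mthfd2, Ddit3, Hspe1 and Hspa8 lost their calls without at least 1 heart, before-AAC replicate 1 or 3 in each (adjusted p up to 0.119).

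Among the marker lists, Myh11 (−0.93), Notch3 (−0.61) and Rgs5 (−0.65) fell of 9 smooth muscle and pericyte genes (1 rose and 5 fell adjusted over the list alone; median −0.61, adjusted p = 0.128). Aif1 (−0.80) was the 1 of 14 macrophage markers that fell. By limma 0 of the 14 changed adjusted over the list alone, and 1 rose and 1 fell at an unadjusted p under 0.05; the median was −0.02, and the test leaned upward (adjusted p = 0.913). Lcn2 (2.15) rose of 2 neutrophil markers (median 1.03, adjusted p = 0.395). Casq1 (1.55) rose and Ckm (−0.34) fell of 3 skeletal muscle markers (median 0.00, mean 0.41, adjusted p = 0.665). Of the 2 brown adipocyte markers Cidea (0.48) rose and Cox7a1 (−0.79) fell (median −0.16, adjusted p = 0.823). Myh11, Notch3, Aif1, Ckm and Cidea were uncalled without before-AAC replicate 3 or Akt-on replicate 3 (adjusted p up to 0.171), and Myh11 stood at −0.60 without Akt-on replicate 2 (adjusted p = 0.138). The markers of lymphocytes (−0.04, adjusted p = 0.876), adipocytes (−0.40, adjusted p = 0.749), erythroid cells (−0.44, adjusted p = 0.395), Schwann cells and neurons (−0.04, adjusted p = 0.749) and mesothelium (−0.28, adjusted p = 0.775) did not pass. On chip 430A the 3'/5' ratio of β-actin was 1.82 ± 0.296 before AAC and 1.12 ± 0.093 with Akt on, and that of Gapdh 1.19 ± 0.122 and 0.868 ± 0.061 (SD, n = 3; exact two-sided permutation p = 0.1 for each, the smallest possible).

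Of the 96 list tests 23 passed at the preset correlation. With camera at an estimated correlation 0 passed, the lowest adjusted p was 0.128, and 7 tests had an unadjusted p under 0.05. By fry, which asks whether the genes of a list move one way and compares them with no other genes, 5 of the 23 passed. These were the angiogenic and endothelial lists in both comparisons with the hearts before AAC, and the cell cycle with Akt on against 4 weeks.

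**Figure D4:**
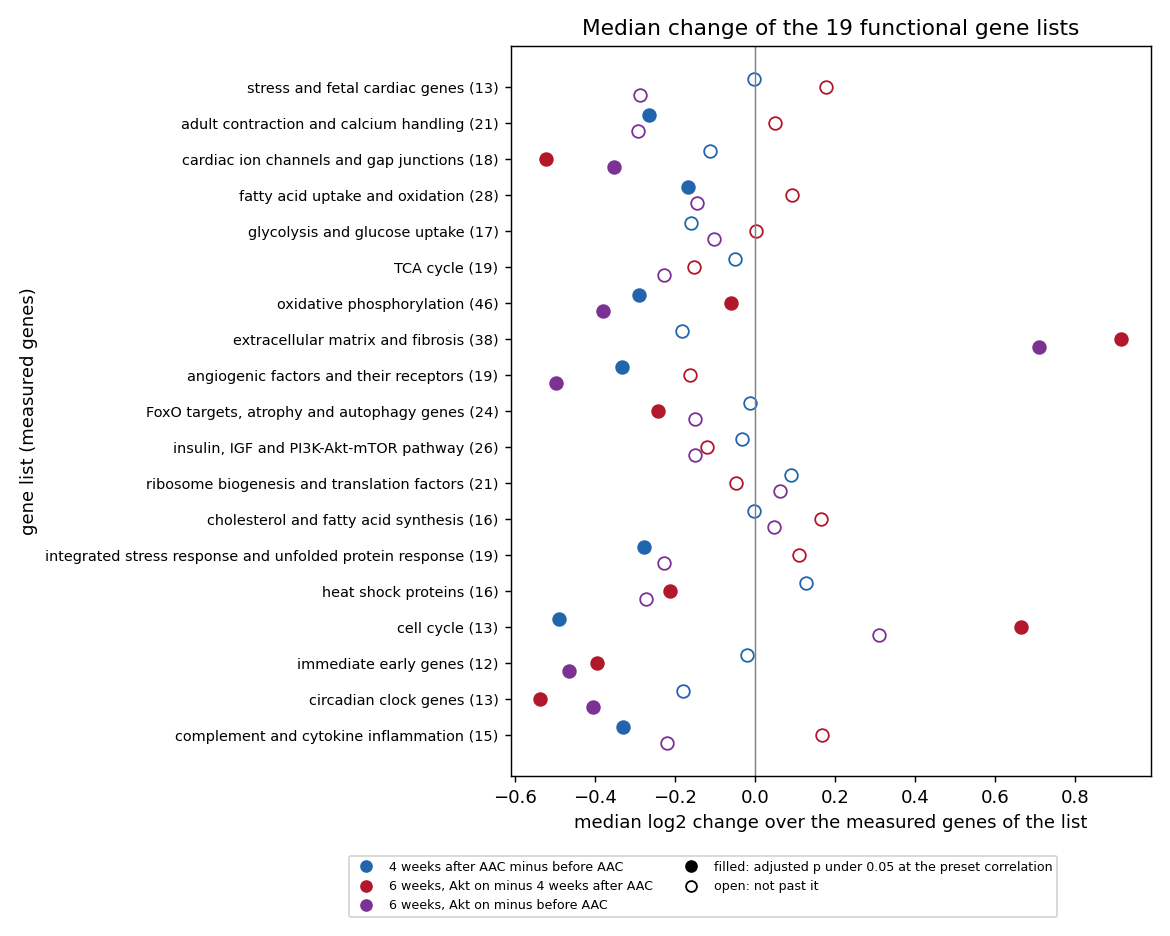
Median log2 change (horizontal axis) over the measured genes of the 19 functional lists (vertical axis, number of genes in brackets) in the 3 comparisons (colours), filled where the adjusted p is under 0.05 at the preset correlation. The extracellular matrix list stands at −0.18, 0.92 and 0.71 and oxidative phosphorylation at −0.29, −0.06 and −0.38, its calls at −0.29 and −0.06 ending under quantile scaling, under which the contraction list at 4 weeks moves from −0.27 to 0.01.

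Whether the changes at 4 weeks were undone with Akt on was asked by setting the first change beside the second. Of the 656 genes changed at 4 weeks, 46 also changed in the second comparison, 39 in the opposite direction (23 risen and then fallen, 16 fallen and then risen) and 7 in the same. Independent lists of these sizes would share 14.2 genes in opposite directions and 14 in the same. In 100 simulated draws of unchanged groups that share the 4-week arrays, the mean was 0.46 opposite genes and the highest 46. The 4-week arrays enter both changes with opposite signs and 3 are too few to split, so the shared arrays add to the count of opposite changes by construction. Opn3 (log2 −1.05, then 2.38), Bex1 (1.21, then −2.12), Cdk1 (−1.14, then 1.71), Col5a1 (−0.59, then 0.94) and Ucp3 (−0.85, then 0.72) were among the 39. Others, named after their values were seen, were Manf (−0.67, then 1.17), the angiotensin receptor gene Agtr1a (0.79, then −0.71) and Cx3cr1 (−0.73, then 1.10). The count of 39 fell to 8, 8 and 3 without before-AAC replicates 1, 2 and 3, and to 12, 4 and 20 without 4-week replicates 1, 2 and 3. Of the 656, 391 were also called with Akt on against before AAC in the same direction and 3 in the opposite one. The arrays before AAC enter both of these changes with the same sign, which favours the same direction by construction.

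Across the 12834 genes, the first change correlated with the second at r = −0.236 (Spearman rho = −0.265, covariance −0.0312), or −0.122 without Akt-on replicate 1. Genes are not independent replicates. In 1000 simulated draws of unchanged groups the shared arrays alone gave a mean r of −0.465 (the central 95% of draws from −0.927 to 0.365) and a mean covariance of −0.0277. The observed covariance differed from that mean by −0.0035.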

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

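In 3 genes limma called both the change at 4 weeks after AAC and the change with Akt on at 6 weeks, each against before AAC, and these lay on opposite sides of 0, with a called difference between them. Bex1 was 1.21 above its level before AAC at 4 weeks and lay below it with Akt on (log2 −0.91), a difference of −2.117 (adjusted p = 0.000969). Manf, a factor of the endoplasmic reticulum, stood at −0.67 and then at 0.50, a difference of 1.165 (adjusted p = 0.000969). Opn3 stood at −1.05 and then at 1.33, a difference of 2.375 (adjusted p = 0.000858). The changes against before AAC had limma adjusted p at 4 weeks and with Akt on of 0.0224 and 0.0252 in Bex1. They were 0.0219 and 0.025 in Manf and 0.038 and 0.00594 in Opn3. The differences of Bex1 and Opn3 between Akt on and 4 weeks stayed called without each of the 9 hearts in turn. That does not cover their calls against before AAC, on which the opposite sides rest.

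The tests in the next paragraphs were added after the results that prompted them were seen. For the tests of antigen presentation, of the neighbourhood of H2-D1 and of the slope for RNA quality, the criterion was written before its own outcome was seen.

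The number of genes called in each comparison was set beside that of the other splits of the same 6 hearts into 3 and 3. The real split was the 1 of 10 with the most calls in each comparison: 656, 553 and 1930 genes by limma, where the highest other split gave 1, 1 and 0. The highest other split gave 779, 846 and 1035 genes at an unadjusted p under 0.05. With 10 splits no share under 0.05 can be reached. RNA quality as the whole cause of the 656 genes, in proportion to the 3'/5' ratio of the controls, was tested on before-AAC replicate 1. Over these called genes the slope of this heart minus the other 2 on the change at 4 weeks was −0.029. The ratios predicted 0.718, and simulated data with that cause gave at least 0.312 over called genes. The observed slope lay below both. The simulated draws gave each gene and heart its own noise and left out deviations that many genes of 1 heart share, so their range is too narrow. The slope therefore does not decide whether RNA quality caused the whole change or a part of it. The SE of the slope (0.0162) came from 1000 draws of the called genes, which are not independent replicates. It does not measure the spread between hearts, and the contrast rests on 1 heart against 2.

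Atrial transcripts differed many-fold between hearts of 1 group. With group means taken out, 8 atrial markers had a median r with Sln of 0.93 over the 9 hearts, and the 5 that had not been looked at before gave 0.919; 6 of the 8 lay between 0.86 and 0.995, while Nr2f2 (0.455) and Bmp10 (0.192) followed Sln less or not. Varying amounts of atrial tissue in the samples may therefore account for this spread. In 2 hearts before AAC Sln, Myl7 and Myl4 all lay above the median of the 6 later hearts. Pressure overload cannot have raised these signals in hearts taken before AAC. The criterion was set after these values were seen, so it decides nothing about induction of atrial isoforms in the later hearts.

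Probe sets of major histocompatibility class I genes differed between the hearts before AAC and all later hearts: of 10 tested, 5 rose at 4 weeks (log2 1.29 to 3.36) and 1 fell. Induction of antigen presentation was argued against by a median change of −0.191 over 7 genes of that pathway (−0.37 to 0.10). RNA quality as the whole cause was argued against by a median ratio of 0.092 over the risen probe sets (SE 0.0128), where 0.718 was predicted. Simulated called genes of that size gave at least 0.691, again with independent noise for each gene and heart. That SE is over the 5 risen probe sets, 4 of them of H2-D1, and not over hearts, and the ratio again rests on before-AAC replicate 1. A strain variant at the locus that changes probe binding might give probe sets called both ways in 1 gene, as in H2-D1, but this was found in the same data and decides nothing. Among the 100 genes nearest to H2-D1, 6% were called against 5.1% of the others (Fisher's exact one-sided p = 0.403), which leaves a variant that spans few genes undecided.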

How the results depend on the processing

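The count of 656 genes at 4 weeks stayed within a factor of 1.5 under 17 of 26 alternatives, the counts of 553 and 1930 under 20 each, and that of 39 opposite genes under 14; the correlation kept its direction under all 25 (−0.328 to −0.122). A similar count did not mean the same genes: of the 656, 477 were also called with the mean of all probe sets, 485 under quantile scaling and 370 without 4-week replicate 3. Of 239 results for named genes 185 were called, and 39 of these held under every alternative in which they were tested. For the differences below the cause was not tested.

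Without a filter 18193 genes were tested and 431 were called at 4 weeks. With the replicate block the counts were 279, 410 and 1641, with 20 opposite genes. With only the 2 groups compared the counts were 963, 213 and 1778, with 21 opposite genes. With 4-week replicates 1 and 3 averaged they were 344, 318 and 2158, with 14 opposite genes. Under quantile scaling and under eBayes without trend the opposite count was 25 each. Without 1 heart the counts ran from 37 to 930, from 201 to 489 and from 973 to 2126, and the opposite count from 3 to 43.

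A further 3 alternatives were chosen after the data had been seen. Without the 4 hearts with the most atrial transcripts limma called 86 genes in the second comparison. This left 1 heart before AAC, with the spread taken from the other groups, so the other counts of 2 and 165 genes (1656 and 2546 at an unadjusted p under 0.05) and of 0 opposite genes (259 unadjusted) say nothing about stability, though the totals above include them. With the atrial score as a covariate there were 683, 661 and 2113, with 47 opposite. With chip 430B on the scale of chip 430A there were 652, 545 and 1911.

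Of the 96 list tests 23 passed by camera, 0 with an estimated correlation (7 at an unadjusted p under 0.05), 6 by fry, and 17 to 30 otherwise. Adult contraction and calcium handling at 4 weeks turned to 0.011 under quantile scaling (adjusted p = 0.555).

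The direction of 5 gene results reversed. Aldoa at 4 weeks gave 0.045 under quantile scaling (adjusted p = 0.795). Per3 in the second comparison gave 0.059 with the highest probe set over both chips (adjusted p = 0.918). With the mean of all probe sets Cox6c at 4 weeks gave 0.097 (adjusted p = 0.77), and against before AAC with Akt on Akt1 gave 1.242 (adjusted p = 0.00284) and Myh6 0.268 (adjusted p = 0.256).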

Other observations

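The clock genes Per1, Tef and Arntl were chosen after their values were seen. Per1 fell by 1.08 with Akt on against before AAC (log2 −1.08, adjusted p = 0.0142) and Tef by 0.84 (log2 −0.84, adjusted p = 0.0106). In the second comparison neither passed by limma (Per1 −0.77, adjusted p = 0.108; Tef −0.48, adjusted p = 0.161). Arntl had a change of 0.81 there and did not pass (adjusted p = 0.0982). The labels give no hour at which the hearts were taken.

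RNA quality was also measured on chip 430B. The 3'/5' ratio of β-actin had means of 1.716, 1.324 and 1.189 before AAC, at 4 weeks and with Akt on (exact two-sided permutation p = 0.2 for the first step and 0.1 for the last group against the first). That of Gapdh had 1.071, 0.884 and 0.836 (exact two-sided permutation p = 0.1 for each).

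Of the pairs of samples with the same number in different groups, 1 of 9 had an r above 0.1, with a range from −0.217 to 0.151 and a median of 0.027 in the other pairs.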
